A study of Mus musculus with 3 samples.

How the data were processed

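3 plates of 384 wells were analysed, 1 each of uncultured E11.5 kidney cells, cultured E12.5 kidney cells and cultured E11.5 kidney cells of C57BL/6 mice. Per the labels' protocols, explants grew in Dulbecco's medium with 10% fetal calf serum, kidneys and explants were dissociated with collagenase, cells were sorted with a FACSAria II, and libraries were made by SORT-seq, in which 1 read carries the well barcode and the molecular identifier and the other the transcript. STAR 2.6.1a, featureCounts 1.5.2 and the mouse build GRCm38.p5 are named per the submitters' processing notes; how they were set is not given in the sources used here. The run codes in the sample descriptions put both cultured plates in 1 sequencing run and the uncultured plate in another.

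The authors deposited 1 table per plate with expected counts of transcripts per gene and well. These are numbers of distinct molecular identifiers corrected for identifiers drawn more than once, as tested on the values: within a tolerance of 0.1, 100% of the values above 0 equal the correction for 4096 possible identifiers. Of them 1.90%, 1.53% and 1.43% were not whole, the smallest at 21.1. Before the data were examined whole counts had been assumed; since no count model was fitted, the values were used as deposited and rounded to whole numbers only for intervals and thinning. The tables list 23820, 22637 and 24092 features, among them merged features whose names end in "-cluster", spike-ins and 3 added sequences. A column of counts without a known well barcode held 4.21%, 4.27% and 4.26% of the plate totals of 4601388, 3302109 and 4158938 and was left out; that it holds such counts was inferred from its name. Gene symbols were used as the tables give them, and no coordinates are given because no genome of the tables' build was used here.

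CPM, counts per 1000000 counts of nuclear-encoded mouse genes, were computed leaving out mitochondrial genes, spike-ins and the added sequences from the total. The 15 wells per plate labelled as controls and the 42 wells per cultured plate labelled as holding more than 1 cell were set apart. Other wells were kept as cells with at least 1000 counts and at most 30% mitochondrial counts, a limit that removed 1 well of the E12.5 cultured plate and none elsewhere. Well P24, outside the labelled control wells, was treated as an ordinary well. No doublet caller was run on 3 plates of sorted cells; wells over 3 times the plate's median count, 32, 7 and 9 in number with 45.6%, 15.0% and 10.6% of the counts, were left out as an alternative. The transcript Gm42418, which overlaps ribosomal RNA sequence, took 5.14%, 2.49% and 2.13% of the counts.

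Each plate pair was compared by CPM of summed counts with exact Poisson 95% intervals, and by the ratio with an exact binomial (Clopper-Pearson) interval of the split of counts. Multi-cell wells were compared with kept single-cell wells of the same plate in the same way. The intervals cover counting error only, and cells are not replicates, so no p-value was computed. A fold against a plate without a count was computed against a floor of 3 counts over the plate and is written with "at least". The exact 95% interval of such a ratio reaches lower. For the E11.5 cultured over the uncultured plate its lower limit was 497-fold against 612-fold for S100a8 and 50.3-fold against 62.6-fold for Htra1. Thinning drew 1000 counts per cell without replacement. Gene lists were summarised by the median log2 ratio of members with at least 10 counts in the pair, by the number of members at least 2-fold higher or lower, and by the percentile of the median among 10000 random lists of the same size matched on mean expression in 10 bins.

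The lists were 13 sets of cell type markers (nephron progenitor, early nephron, podocyte, proximal tubule, loop of Henle and distal tubule, ureteric epithelium, stroma, endothelium, macrophage and other leukocyte, erythroid, neural and neural crest, skeletal muscle, coelomic epithelium and gonad) and 12 programmes (Lgr receptors and Wnt pathway, proliferation, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, dissociation and immediate early, matrix and myofibroblast, basement membrane, epithelial adhesion and polarity, renal transcription factors, imprinted growth genes, interferon response). Aqp2 and Amh were listed in none of the tables.

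For clusters, kept cells of all plates were scaled to 10000 counts and log-transformed after adding 1, and 1500 variable genes, 20 principal components, 15 neighbours and Leiden resolution 1.0 were used with seed 0. Tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. A cluster was named when at least 3 markers of a list were at least 2-fold above the other cells and found in at least 10% of its cells, more than for any other list, and no other list held more of its 10 leading genes. These naming thresholds were set after the clusters were seen.

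The filters, comparisons, marker lists, gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule names Lgr6, Lgr4, Lgr5, Six2, Cited1, Wt1, Pax2 and the reporters; per plate pair, up to 12 genes per direction with the largest ratio, ranked by the interval bound nearest to 1, among genes with at least 50 counts found in at least 10% of the higher plate's cells, leaving out mitochondrial and ribosomal protein genes, spike-ins and unnamed models; up to 4 members of each list, the 2 highest and the 2 lowest; the 10 leading genes of each cluster; and up to 8 genes per direction within progenitor-like cells, a part that was not reached because the cultured plates had under 20 such cells. Some genes it takes are not reported here, though they enter counts and list medians. Its extension to multi-cell wells, the grouping of progenitor-like and epithelial cells for Lgr6 and the count of wells over 60000 counts were chosen after the data were seen.

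The procedure was tested on simulated data for the E11.5 cultured and uncultured plates, with counts drawn for 28868 genes of which 200 were changed, 50 per fold size. The changed genes were drawn from those with at least 100 uncultured counts, and unchanged genes were scored only with at least 50 simulated counts in the pair. The results therefore do not speak to ratios that rest on few counts. All 50 genes of each size had the right direction (100%). With Poisson counts the intervals covered the true ratio for 94.0% of genes raised 2-fold, 96.0% lowered to 0.5-fold, 94.0% raised 4-fold, 96.0% lowered to 0.25-fold and 95.7% of 10744 unchanged genes. With variation between cells added, coverage was 84.0%, 92.0%, 90.0%, 92.0% and 91.9%, so intervals are too narrow where cells vary. A list of 15 genes raised 2-fold lay at percentile 100 and lists of unchanged genes at 35.0 and 81.0. Clustering of cells drawn from the cluster sums returned the clusters (adjusted Rand index 1.0), whereas on the real cells at 50% of their counts the index was 0.649 with 16 clusters. Alternatives covered the count minimum, weighting of cells, scaling, control-well background, deep wells, plate columns, list minimum, thinning and clustering; those added after seeing the data are named as such in the closing part.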

Results

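Transcripts were counted in single cells of the mouse embryonic kidney by SORT-seq, a plate method in which sorted cells lie in the wells of a 384-well plate and each transcript carries a molecular identifier (UMI). The series asks which cells of the developing kidney express Lgr6, a receptor of the R-spondin and Wnt pathway, and what its progeny become. 3 plates were measured, 1 per group. The first held cells of E11.5 kidneys from Lgr6-EGFP-IRES-CreERT2 mice taken without culture. The second held cells of E12.5 kidneys cultured for 5 days, and the third cells of E11.5 kidneys cultured for 7 days by its title and 5 days by its stage label, both from mice that also carried a Cre-dependent ROSA26-tdTomato reporter. Culture, genotype and sequencing run differed together between the uncultured plate and the cultured plates, which shared 1 run, and for the E12.5 cultured plate the starting stage differed too. How cells were gated at the sort is not given in the sources used here. With 1 plate per group there was no replicate, so no test was run. Intervals are 95% intervals (exact Poisson for counts, exact binomial for shares and ratios) and cover counting error only. The limit given for a count of 0 is that of 3 counts over the total.

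After wells labelled as controls and wells labelled as holding more than 1 cell were set apart, 337 of 369 ordinary wells of the uncultured plate were kept as cells (91.3%, 88.0 to 94.0). On the E12.5 cultured plate 200 of 327 were kept (61.2%, 55.6 to 66.5), and on the E11.5 cultured plate 300 of 327 (91.7%, 88.2 to 94.5). Kept wells held 4159791, 2349129 and 3210838 transcript counts of nuclear-encoded genes in this order, with medians of 6732, 9212 and 8992.5 counts and of 3310.0, 3900.5 and 3800.0 genes per well. The median share of mitochondrial transcripts was 7.28% on the uncultured plate, 3.61% on the E12.5 cultured plate and 3.49% on the E11.5 cultured plate. Counts were unevenly spread over uncultured wells: 8 wells with over 60000 counts held 29.0% of them, and the deepest well alone, with 364620, held 8.77%. In the 15 control wells per plate the median was 632, 129 and 150 counts, and 7 uncultured control wells reached 1000. Fewer wells were kept in the lower rows of the E12.5 cultured plate, 82.4% in rows A to G, 53.8% in rows H to O and 3 of 24 in row P. On the E11.5 cultured plate these shares were 94.96%, 95.7% and 11 of 24.

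**Figure D1:**
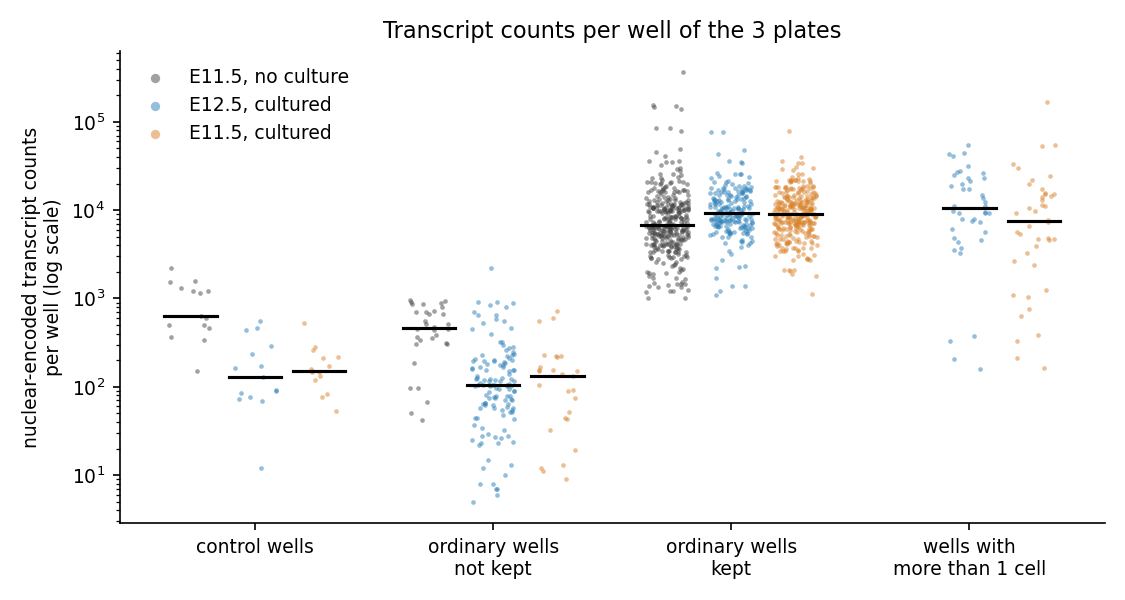
Transcript counts of nuclear-encoded genes per well on a log axis, for each plate and kind of well, with 1 point per well and a black bar at the median. Kept wells have medians of 6732, 9212 and 8992.5 counts, above the control-well medians of 632, 129 and 150.

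Clustering of the 837 kept cells gave 15 clusters of 17 to 107 cells, of which 7 could be named from marker lists. Uncultured and cultured cells shared few of them. 7 clusters with cultured cells only held 85.5% of the E12.5 cultured cells and 87.3% of the E11.5 cultured cells, and 2 clusters held uncultured cells only. A cluster made mostly of 1 library may be that library and not a cell type. The nephron progenitor-like cluster, led by Six2, Eya1, Uncx, Spock2 and Cited1, held 92 uncultured cells (27.3% of the plate, 22.6 to 32.4), 10 E12.5 cultured cells (5.0%, 2.42 to 9.003) and 5 E11.5 cultured cells (1.67%, 0.543 to 3.85). The cultured shares were 1.5% and 0.333% at a clustering resolution of 2.0 and 13.5% and 8.33% with each plate clustered alone. A cluster led by Lyz2, C1qa, C1qb and C1qc was macrophage and other leukocyte-like and held 17, 4 and 15 cells. An endothelium-like cluster led by Cd93, Plvap and Pecam1 held 17, 1 and 2 cells. Neural and neural crest-like clusters, 1 with Fabp7 among its leading genes and the other led by Prph and Tubb3, together held 37, 1 and 11 cells. Stroma-like clusters held no uncultured cell and 62 and 89 cultured cells: 1 was led by Fmo1, Lum, Myh11 and Dcn, and the other by genes of the response to low oxygen (Ero1l, Slc2a3, Bnip3, Ndrg1) with Penk, Dlk1 and Postn as its stroma markers. The stroma-like share of uncultured cells was 14.8% at a resolution of 2.0, 20.5% with the plate clustered alone and 54.0% when cells were assigned from markers without clusters, which gave 88.5% and 91.7% of the cultured cells. These shares rest on genes that themselves differ between the plates, and the sort gate and the depth gap can set them, so they are given as values and not compared.

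The other 8 clusters stayed unnamed and held 51.6%, 61.0% and 59.3% of the 3 plates' cells. An epithelial cluster with 37, 13 and 5 cells, led by Cdh16, Cldn6, Epcam, Krt18 and Krt8, had 10 early nephron markers and 10 ureteric markers and so got neither name. A cluster with Igf1, Osr2, Hoxd13 and the estrogen receptor gene Esr1 among its leading genes held 84 cells of the E11.5 cultured plate (28.0%), 2 of the E12.5 cultured plate (1.0%) and no uncultured cell. It had 6 stroma markers (Col1a1, Col1a2, Col3a1, Dcn, Lum and Dlk1), none of them among its leading genes, while Osr2 is of the proximal tubule list, so the rule on leading genes, set after the clusters were seen, kept it out of the stroma-like class. Without that rule the stroma-like share was 32.0% of the E12.5 cultured and 57.7% of the E11.5 cultured cells. Clusters led by Crabp1, Ebf2, Foxd1 and Ntn1 and by Clstn2, Sfrp2, Col9a1 and Col2a1 held 97 and 40 uncultured cells and no cultured cell. The first had 2 stroma markers (Foxd1 and Ntn1) and 2 skeletal muscle markers (Actc1 and Tnnt1), and the second 2 stroma markers (Tbx18 and Cxcl12). Both fell short of the 3 markers needed for a name. That no uncultured cell was named stroma-like thus does not show that stroma was absent before culture.

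Lgr6 was scarce on every plate. A transcript was counted in 9 of 337 uncultured cells (2.67%, 1.23 to 5.01), 4 of 200 E12.5 cultured cells (2.0%, 0.548 to 5.04) and 8 of 300 E11.5 cultured cells (2.67%, 1.16 to 5.19), and in 0 of 15 control wells of each plate, which allows a share of up to 20%. Over all kept wells its level was 2.16 (0.989 to 4.11), 2.13 (0.691 to 4.97) and 3.74 (1.93 to 6.53) counts per 1000000 counts of nuclear-encoded genes (CPM), so no difference was detectable at this depth. On the uncultured plate all 9 cells with Lgr6 lay in the nephron progenitor-like cluster (6 of 92) or the epithelial cluster (3 of 37), together 6.98% of 129 cells (3.24 to 12.8; median depth 10025 counts). In the 208 other uncultured cells there was none, which allows up to 1.44% (median depth 5947). The 17 macrophage-like cells among them, too few to tell, allow up to 17.6% (median depth 6312). By level the 129 cells stood at 4.81 CPM (2.20 to 9.14) against at most 1.31 CPM in the other cells. The grouping of these clusters was made after the cells with Lgr6 had been seen. All 9 uncultured cells with Lgr6, those of the epithelial cluster included, had at least 2 of Six2, Cited1, Meox1, Crym and Dapl1 detected. That choice of cells depends on depth. On the cultured plates 1 of 23 and 0 of 10 nephron progenitor-like and epithelial cells had Lgr6, against 3 of 177 and 8 of 290 other cells. With every cell thinned to 1000 counts, Lgr6 was left in 0, 0 and 2 cells. Its relative Lgr4 stood at 104 (94.1 to 114), 55.8 (46.6 to 66.2) and 53.9 (46.2 to 62.5) CPM, and Lgr5 at 4.57, 2.55 and 1.56 CPM.

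The count tables also list 3 added sequences: the knock-in transcript EGFP_IRES_Cre, tdTom for the lineage reporter, and NeoR, the resistance gene used in targeting. EGFP_IRES_Cre was found in 2.97% of uncultured cells, 39.0% of E12.5 cultured cells and 25% of E11.5 cultured cells, or 0%, 4.5% and 3.0% after thinning to 1000 counts. Its level was 2.64, 43.8 and 30.5 CPM, 16.6-fold (8.89 to 34.3) and 11.54-fold (6.18 to 23.9) higher on the cultured plates than on the uncultured plate. On the uncultured plate 8 of the 129 nephron progenitor-like and epithelial cells had EGFP_IRES_Cre, against 2 of 208 others. tdTom was counted in 2 uncultured cells (0.593%), whose mice carried no such reporter by the labels, and in 46.0% and 43.3% of the cultured cells, or 0%, 6.0% and 7.0% after thinning. Its level was 0.481, 75.3 and 63.8 CPM. Against the 2 uncultured counts this was a 157-fold (42.7 to 1304) and a 133-fold (36.3 to 1104) ratio. tdTom was counted in 7 of 19 cultured macrophage-like cells (36.8%, 16.3 to 61.6; median depth 13354) and in 215 of the other 481 cultured cells, nephron cells among them (44.7%, 40.2 to 49.3; median depth 8991.5). The other cells' share was thus not told apart from that of macrophages by share, while by level it was lower in macrophage-like cells, 29.8 against 70.4 CPM, a ratio of 0.424 (0.169 to 0.882). In nephron progenitor-like and epithelial cells tdTom stood at 51.2 CPM and in the other cultured cells at 70.0 CPM, a ratio of 0.732 (0.435 to 1.16). NeoR stood at 46.2, 70.7 and 81.6 CPM.

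**Figure D2:**
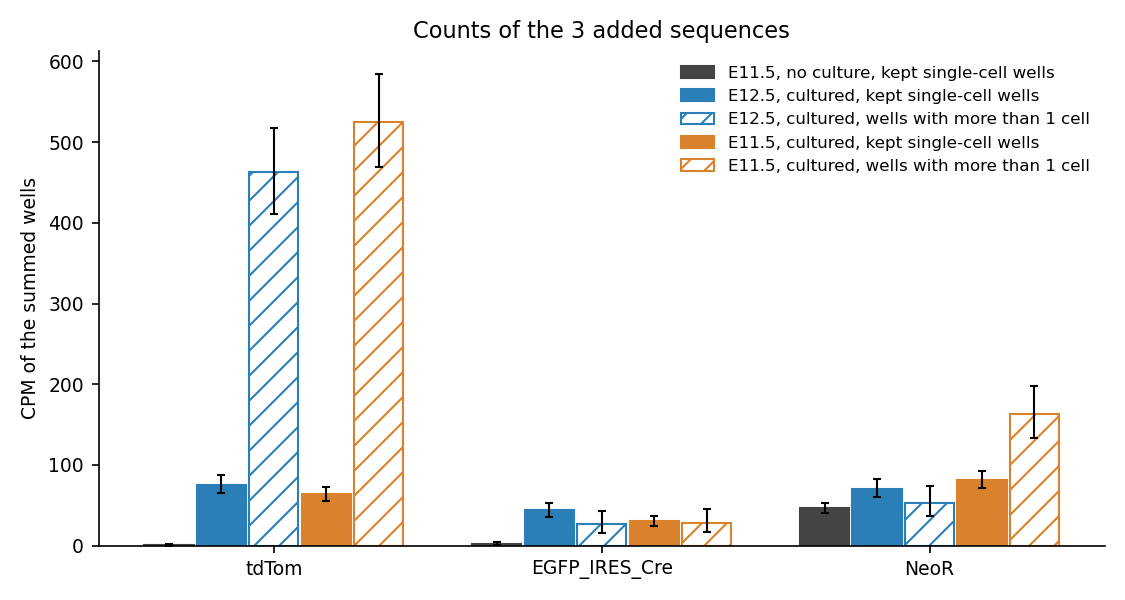
CPM of tdTom, EGFP_IRES_Cre and NeoR, summed over kept single-cell wells (filled) and wells labelled as holding more than 1 cell (hatched) of each plate; bars start at 0 and error bars are 95% Poisson intervals for counting error. tdTom reaches 462 and 524 CPM in the wells with more than 1 cell and 75.3 and 63.8 CPM in the single-cell wells.

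The comparison of the E11.5 cultured plate with the uncultured plate asks how kidney cells of 1 embryonic stage differ after explant culture. Genes of the nephron progenitor were far lower after culture. Six2, the transcription factor that keeps progenitors undifferentiated, stood at 42.4 CPM (35.5 to 50.1) against 312 (295 to 329), 7.36-fold lower (6.17 to 8.86). Pax2 was 9.33-fold lower (7.63 to 11.54), Cited1 5.52-fold (3.97 to 7.85) and Wt1 2.77-fold (2.56 to 3.004). Stromal, matrix, hypoxia and immediate early genes were higher: Dcn, the matrix proteoglycan decorin, stood at 1826 CPM (1779.8 to 1874) against 24.0 (19.6 to 29.2), 76.0-fold higher (62.3 to 93.5). After thinning to 1000 counts Six2 was found in 19.6% of uncultured and 6.0% of E11.5 cultured cells (47.8% and 17.3% unthinned), Pax2 in 21.4% and 2.67% (56.7% and 10.0%), Wt1 in 45.4% and 22% (84.0% and 64.3%), and the collagen gene Col1a1 in 38.9% and 93.7% (73.0% and 100%).

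**Figure D3:**
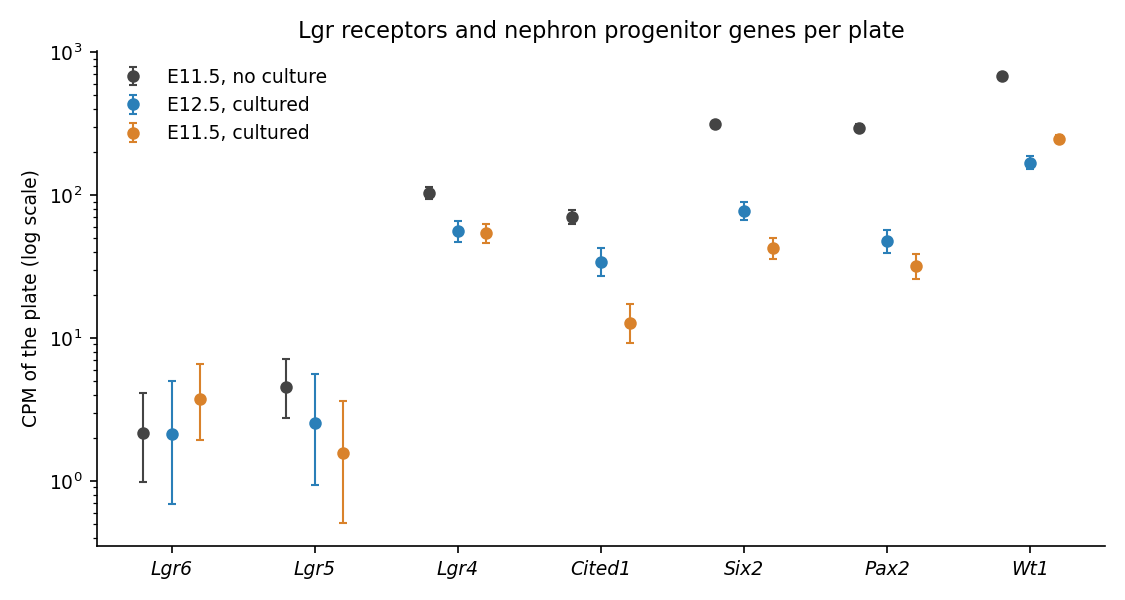
CPM of Lgr6, Lgr5, Lgr4, Cited1, Six2, Pax2 and Wt1 in each plate on a log axis, with 95% Poisson intervals for counting error. Six2 lies at 312 CPM on the uncultured plate and at 77.6 and 42.4 CPM on the cultured plates, while the intervals of Lgr6 overlap.

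Among all genes ranked by size, the largest E11.5 cultured over uncultured ratios apart from Dcn included those of Myh11, smooth muscle myosin (57.5 against 0.240 CPM, 238-fold, 42.3 to 9466, on 1 uncultured count), Aldh1l2 (62.6-fold, 30.03 to 157), Igfbp7 (574 against 15.4 CPM, 37.3-fold, 29.1 to 48.6) and Trib3, a stress-induced pseudokinase (181-fold, 32.0 to 7215, on 1 uncultured count). Htra1, a secreted protease, and Sprr1a had no uncultured count and were at least 62.6-fold and 44.6-fold higher against a floor of 3 counts over the plate, with 48.7% of the Sprr1a counts in 1 well. So were the granulocyte genes S100a8 (441 CPM, at least 612-fold), S100a9 (338-fold), Mpo (262-fold) and Elane (258-fold), of whose counts 91.8% lay in 5 wells. In the other direction Hmga2, a chromatin protein of immature cells, stood at 94.99 against 1297 CPM, 13.7-fold lower (12.2 to 15.4). Uncx and Meox1, homeobox genes of the progenitor list, were 17.7-fold (13.7 to 23.3) and 24.7-fold (12.8 to 54.6) lower. Lhx1 of the early nephron was 41.8-fold lower (17.7 to 129.9), the endothelial gene Plvap 31.6-fold (17.9 to 61.5), the cartilage collagen Col2a1 29.8-fold (16.9 to 58.2) and the muscle actin Actc1 24.6-fold (14.8 to 44.3). Fndc3c1 and Plch1 were 40.7-fold and 39.4-fold lower, the second on 3 counts. The globin genes Hbb-y and Hba-a1 had no count after culture, at least 452-fold and 382-fold lower, but 95.6% and 94.8% of their uncultured counts lay in 1 well. Ppbp, a platelet chemokine with 40.9% of its uncultured counts in 1 well, was at least 27.8-fold lower.

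By gene list, the nephron progenitor list had a median log2 ratio of -2.49 over 12 measured members, at percentile 0 among 10000 matched random lists, as a description of these libraries. Of these members 9 were at least 2-fold lower and 0 at least 2-fold higher, with Itga8 1.58-fold higher (1.33 to 1.88). In even-numbered plate columns the median was -3.16. The early nephron list stood at -1.03 (percentile 0.01; 6 of 12 members at least 2-fold lower, 1 higher), with Pax8 11.51-fold lower (8.48 to 15.99) and Wnt4 at 147 against 159 CPM. Renal transcription factors stood at -1.41 (percentile 0; 9 of 16 lower, 0 higher), and 7 members of that list are also cell type markers; Hoxa11 was 1.27-fold higher (1.02 to 1.58). The podocyte list had a median of 1.10 (percentile 99.4; 6 of 11 higher, 0 lower), with Podxl at 24.98 against 28.8 CPM and 56.4% of its cultured counts in 1 well. Medians of the tubule lists rested on few counts: proximal tubule 1.07 over 4 members (percentile 88.1; mean -0.08), with Osr2 3.28-fold higher (2.67 to 4.06). The loop of Henle and distal tubule list stood at 1.73 over 7 members (percentile 98.1), which turned to -1.24 with members of at least 50 counts. In that list the 11 counts of the salt transporter Slc12a1 lay in 1 cultured well, and Mecom was 3.89-fold lower (3.11 to 4.92). The ureteric epithelium list stood at 0.54 (9 members; percentile 74.1) and at -2.08 in odd columns, with Krt19 9.85-fold higher (3.87 to 32.0) and Calb1, at 37.8 CPM without culture, at least 40.5-fold lower. For epithelial adhesion and polarity the median was -0.37 (percentile 2.38) and the mean 0.00, with 4 of 16 members higher and 4 lower, among them Cldn4 4.10-fold higher (1.58 to 12.6) and Prom1 3.10-fold lower (2.28 to 4.29).

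Stroma genes had a median of 2.37 (16 members; percentile 100; 11 higher, 2 lower), with Penk, the opioid precursor gene, 34.7-fold higher (28.8 to 42.3) but the early stromal factors Foxd1 3.59-fold (3.17 to 4.08) and Ntn1 3.61-fold (2.74 to 4.81) lower. Matrix and myofibroblast genes stood at 2.78 (percentile 100; 15 of 16 higher), with Ctgf 29.1-fold (13.8 to 73.5) and Tagln 27.2-fold (20.96 to 35.8) higher and Tgfbi at 420.1 against 443 CPM; 4 members are also cell type markers. Basement membrane genes stood at 0.82 (percentile 99.8; 7 of 14 higher, 1 lower), with Lamb2 5.03-fold higher (4.06 to 6.26) and Lama1 2.21-fold lower (1.54 to 3.21). The dissociation and immediate early list had the highest median, 2.97 (percentile 100; 15 of 17 higher, 1 lower): Junb stood at 588 against 29.1 CPM and the heat-shock gene Hspa1a was 24.0-fold higher (10.7 to 66.7), whereas Hsph1 was 3.64-fold lower (3.08 to 4.31). Hypoxia and glycolysis genes stood at 1.91 (percentile 100; 17 of 20 higher, 0 lower), with Ero1l 12.96-fold (9.46 to 18.2) and Gapdh 1.51-fold (1.46 to 1.56) higher. Cholesterol synthesis genes stood at 0.79 (percentile 99.9; 5 of 14 higher). The interferon response list stood at 2.09 over 7 members (percentile 99.6), with Ifitm3 at 419 against 19.95 CPM and Rsad2 2.99-fold lower (1.34 to 7.53). Imprinted growth genes stood at 0.05 with 2 of 11 higher and 2 lower, Meg3 at 2399.9 against 334 CPM and Peg3 at 371 against 1271.

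Proliferation genes were lower, with a median of -1.09 (percentile 0; 13 of 21 members lower, 0 higher): Rrm2, a subunit of ribonucleotide reductase, was 4.99-fold lower (4.37 to 5.71) and Pcna 1.27-fold (1.13 to 1.42). Mki67 was found in 27.0% of uncultured and 11% of E11.5 cultured cells after thinning (70.3% and 28.3% unthinned), and Top2a in 38.0% and 14% (77.7% and 41.7%). Oxidative phosphorylation genes stood at -0.64 (percentile 0.93; 4 of 18 lower), with Uqcrq 2.38-fold lower (2.13 to 2.67) and Ndufb9 at 123 against 131 CPM. Lgr receptors and the Wnt pathway stood at -0.12 (percentile 27.2; 3 of 19 higher, 3 lower), with the feedback inhibitor Nkd1 3.07-fold higher (2.67 to 3.53), Dkk1 3.22-fold lower (1.69 to 6.64) and Lgr4 1.92-fold lower (1.61 to 2.31). Endothelium stood at -1.42 (percentile 0; 6 of 10 lower, 0 higher), with Cdh5 at 21.2 against 26.2 CPM and 66.3% of its cultured counts in 1 well. Skeletal muscle stood at -3.74 (5 of 6 lower), with Myog at least 23.0-fold lower, and erythroid at -6.87 (8 of 8 lower). Macrophage and other leukocyte genes stood at 0.84 (percentile 99.5; 2 of 10 higher) and at -0.039 without wells over 3 times the plate's median count, with Lyz2 6.87-fold higher (5.88 to 8.07) and Csf1r at 85.2 against 77.6 CPM. Of the cultured Lyz2 counts 39.4% lay in 1 well and 79.7% in 5 wells. Neural and neural crest genes stood at 1.73 (percentile 99.9; 8 of 10 higher, 1 lower), with Tubb3 25.6-fold higher (14.7 to 48.8; 62.8% of its cultured counts in 1 well) and Elavl4 3.57-fold lower (2.54 to 5.10). The coelomic epithelium and gonad list stood at 0.58 over 4 members (percentile 53.5), with the mesothelial gene Upk3b 13.99-fold higher (5.64 to 44.8; 48.2% of its cultured counts in 1 well). Of 76 genes taken by the naming rule for this comparison, 71 kept their direction under every alternative and 48 moved by over 1.5 times under at least 1 of them.

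**Figure D4:**
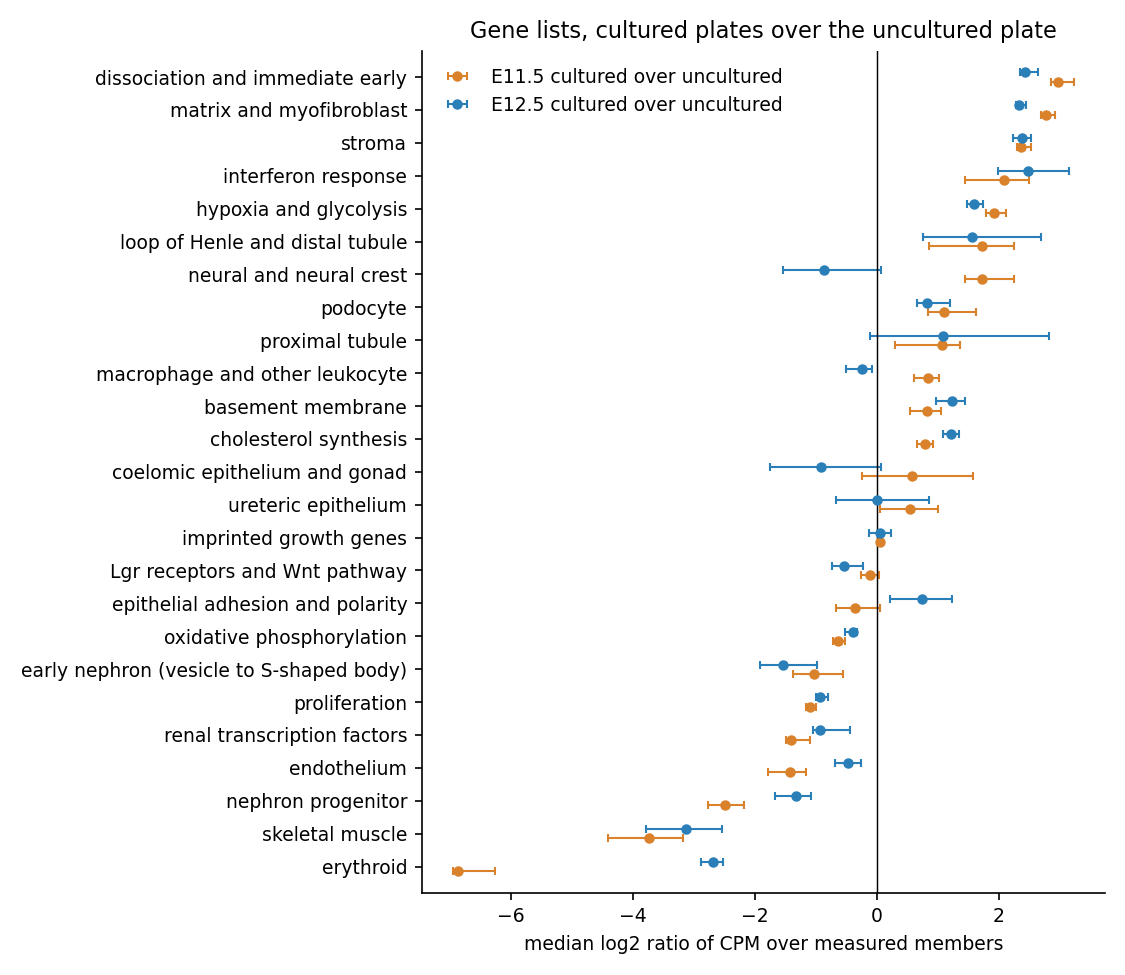
Median log2 ratio of CPM over the measured members of each of 25 gene lists, for the E11.5 and the E12.5 cultured plate over the uncultured plate; error bars show how far resampling of the counts moves each median. The nephron progenitor list lies at -2.49 and -1.33 and the stroma list at 2.37 and 2.38.

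The comparison of the E12.5 cultured plate with the uncultured plate adds a later starting stage to culture, and its ratios share the uncultured plate with those above, so any peculiarity of that plate enters both. Progenitor genes were again lower after culture and stroma list genes higher. Six2 stood at 77.6 CPM (66.7 to 89.7), 4.02-fold lower (3.45 to 4.73), Pax2 was 6.22-fold lower (5.12 to 7.62), Wt1 4.06-fold (3.66 to 4.53) and Lgr4 1.86-fold (1.52 to 2.28). Cited1 was 2.07-fold lower (1.61 to 2.68) over the whole plate but not in even columns, where its log2 ratio was 0.027. The proenkephalin gene Penk stood at 1315 CPM (1269 to 1362) against 27.2 (22.4 to 32.7), 48.4-fold higher (40.1 to 58.9). After thinning, Six2 was found in 6.0% of E12.5 cultured cells (20.5% unthinned), Cited1 in 3.0% (16%) against 4.15% (21.7%) without culture, Wt1 in 11% (50%), Pax2 in 2.5% (21%) and Col1a1 in 88.5% (99.5%).

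The largest ratios in favour of the E12.5 cultured plate included those of Actg2 (252 against 2.40 CPM, 105-fold, 56.6 to 219.7), Myh11 (737-fold, 131 to 29165, on 1 uncultured count; 42.2% of its cultured counts in 1 well), Dcn (66.8-fold, 54.8 to 82.3), Igfbp7 (1003 against 15.4 CPM, 65.2-fold, 50.8 to 84.9), Ogn (31.7-fold, 22.2 to 46.8) and Eln, the elastin gene (39.4-fold, 31.3 to 50.2; 45.2% of its cultured counts in 1 well). The protease inhibitor Serpina3g was 45.6-fold higher (22.7 to 107), and Fmo1 and Trib3 were 202-fold (35.5 to 8042) and 159-fold (27.9 to 6364) higher on 1 uncultured count each. Cpxm2 and Htra1, with no uncultured count, were at least 52.5-fold and 35.4-fold higher. Lower on the cultured plate were Hmga2 (96.2 against 1297 CPM, 13.5-fold, 11.8 to 15.5), Eya1, a partner of Six2 (17.9 against 208 CPM, 11.7-fold, 8.55 to 16.3), and the retinoic acid binding protein genes Crabp1 (10.4-fold, 8.52 to 12.9) and Crabp2 (11.1-fold). Lin28b, which blocks let-7 maturation, Arg1 and Zfp990 had no count after culture and were at least 14.1-fold, 20.1-fold and 11.48-fold lower. Snrpf was 10.6-fold, Snhg6 12.4-fold, Fndc3c1 17.03-fold and Actc1 12.3-fold lower, and Ppbp, with 40.9% of its uncultured counts in 1 well, 61.1-fold (10.7 to 2431) on 1 cultured count.

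By list, the nephron progenitor median was -1.33 over 12 members (percentile 0; 7 at least 2-fold lower, 0 higher), at -2.42 in odd columns and -0.74 with every cell weighted equally. Meox1 was 11.6-fold lower (6.81 to 21.5), while Osr1 stood at 71.9 against 71.5 CPM and Itga8 was 1.48-fold higher (1.22 to 1.79). Early nephron genes stood at -1.54 (percentile 0; 7 of 12 lower, 1 higher), with Pax8 6.07-fold lower (4.67 to 8.03) and Wnt4 1.38-fold higher (1.22 to 1.55). Renal transcription factors stood at -0.94 (percentile 0.01; 8 of 17 lower, 2 higher), with Hoxa11 2.13-fold higher (1.73 to 2.62). The podocyte list stood at 0.82 (percentile 97.9; 5 of 10 higher, 0 lower), with Ptpro 7.08-fold higher (2.58 to 24.2). Proximal tubule genes stood at 1.09 (7 members; percentile 91.4), with the transcription factor Hnf4a at least 9.44-fold higher, counted in 4 cultured wells. The loop of Henle and distal tubule list stood at 1.56 (7 members, percentile 98.3, 5 higher) and at -0.63 with members of at least 50 counts. In it Sostdc1 was 26.6-fold higher (8.53 to 134) and Mecom 1.70-fold lower (1.42 to 2.06), with 44.0% of the cultured Mecom counts in 1 well. Ureteric epithelium stood at -0.00 (10 members; mean 0.03; 4 higher, 3 lower), with the receptor gene Ret 10.2-fold lower (3.30 to 50.8) and Calb1 88.9-fold lower (15.7 to 3524), on 3 and 1 cultured counts. Epithelial adhesion and polarity genes stood at 0.75 (percentile 98.3; 7 of 16 higher, 0 lower) but at -0.086 in odd columns; Cdh16, kidney cadherin, was 8.96-fold higher (5.20 to 16.4), Cldn4 10.0-fold (4.16 to 29.2; 41.2% of its cultured counts in 1 well) and Ezr 1.93-fold lower (1.55 to 2.42).

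The stroma median was 2.38 (percentile 100; 12 of 16 higher, 1 lower), with Acta2, smooth muscle actin, 24.9-fold higher (21.7 to 28.7) and Foxd1 1.96-fold lower (1.75 to 2.19). Matrix and myofibroblast genes stood at 2.33 (percentile 100; 15 of 16 higher), with Ctgf 31.9-fold higher (15.02 to 80.9) and Tgfbi at 423 against 443 CPM. Basement membrane genes stood at 1.24 (8 of 14 higher, 1 lower), with Lamb2 5.34-fold higher (4.29 to 6.70) and Col4a5 2.59-fold lower (1.65 to 4.21). Immediate early genes stood at 2.42 (percentile 100; 14 of 17 higher, 1 lower), with Fosb 17.4-fold (14.8 to 20.6) and Junb 15.8-fold (13.1 to 19.3) higher and Hsph1 3.32-fold lower (2.76 to 4.0). Hypoxia and glycolysis genes stood at 1.59 (percentile 100; 17 of 20 higher), with P4ha1 5.58-fold higher (4.75 to 6.60) and Hk2 at 66.8 against 66.1 CPM. Cholesterol synthesis stood at 1.22 (percentile 100; 8 of 14 higher), with Fdps 6.99-fold higher (4.18 to 12.2). The interferon response list stood at 2.48 (7 members; 6 higher, 1 lower), with Ifitm3 21.3-fold (17.01 to 27.0) and Oasl2 8.26-fold (3.96 to 19.3) higher and Rsad2 17.5-fold lower (2.92 to 713) on 1 cultured count. Imprinted growth genes stood at 0.04, with Meg3 5.12-fold higher (4.81 to 5.44) and Peg3 2.23-fold lower (2.10 to 2.37).

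Proliferation genes stood at -0.93 (percentile 0; 8 of 21 lower, 0 higher), with Ccnb1 3.25-fold lower (2.75 to 3.87) and Mcm5 1.16-fold (1.03 to 1.31). After thinning, Mki67 was found in 11% and Top2a in 18.0% of E12.5 cultured cells (34.5% and 49.0% unthinned). Oxidative phosphorylation genes stood at -0.40 (percentile 7.97), with Ndufa4 2.30-fold lower (2.08 to 2.54). Lgr receptors and the Wnt pathway stood at -0.54 (percentile 1.65; 2 of 19 higher, 3 lower), with Nkd1 3.19-fold higher (2.76 to 3.69) and Sp5, a Wnt target, at least 4.52-fold lower. Of the other cell types, endothelium stood at -0.48 (percentile 6.46), with Plvap 3.78-fold lower (2.97 to 4.93) and 80.9% of its cultured counts in 1 well. Macrophage and other leukocyte genes stood at -0.24 (percentile 26.8), with Csf1r 2.601-fold lower (2.01 to 3.42), and at 0.33 in odd columns. Neural and neural crest genes stood at -0.88 over 7 members (percentile 1.7), with Elavl4 4.76-fold lower (3.08 to 7.69) but Tubb3 10.1-fold higher (5.55 to 19.8; 77.2% of its cultured counts in 1 well). Skeletal muscle stood at -3.13 (5 of 6 lower), with Myog at least 16.8-fold lower, and coelomic epithelium and gonad at -0.91 over 3 members. The erythroid median was -2.69 (8 of 8 lower) and became 1.20 without wells over 3 times the plate's median count, which removes the uncultured well that held most globin counts. Of 75 genes taken here, 69 kept their direction under every alternative and 39 moved by over 1.5 times under at least 1.

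Between the cultured plates, which differ in starting stage and, by title, in days of culture, the stroma list had a median near 0 over members that went both ways, and lists of several other cell types did not. The stroma median of the E11.5 over the E12.5 cultured plate was 0.02 and the mean -0.04 (16 members; 0 at least 2-fold higher, 0 lower), with Dlk1 1.70-fold (1.60 to 1.80) and Postn 1.78-fold (1.61 to 1.96) higher and Foxd1 1.83-fold (1.57 to 2.13) and Acta2 1.95-fold (1.84 to 2.06) lower. Neural and neural crest genes were higher on the E11.5 cultured plate, with a median of 1.95 (percentile 100; 8 of 10 higher, 0 lower); Sox10, the neural crest factor, stood at 29.3 CPM against no count, at least 22.9-fold higher. Macrophage and other leukocyte genes were higher too, at 1.17 (percentile 100; 8 of 10 higher, 0 lower), with Lyz2 6.58-fold (5.41 to 8.08) and Ptprc 3.54-fold (1.88 to 7.23) higher. Of the Lyz2 counts 39.4% on the E11.5 and 41.2% on the E12.5 cultured plate lay in 1 well. So did 41.7% of the 12 E12.5 cultured counts of Ptprc. The macrophage-like cluster held 15 E11.5 cultured and 4 E12.5 cultured cells. The nephron progenitor list had no stable direction. Six2 was 1.83-fold lower (1.46 to 2.30), Cited1 2.67-fold (1.81 to 3.99) and Pax2 1.499-fold (1.14 to 1.98) on the E11.5 cultured plate, with a list median of -0.88 (percentile 0; 5 of 12 lower, 0 higher), but in odd columns the list stood at 0.42, Six2 at 0.68, Cited1 at 0.42 and Pax2 at 0.11 (log2). Wt1 was 1.47-fold higher (1.30 to 1.66), Lgr4 stood at 53.9 against 55.8 CPM and Eya1 at 24.6 against 17.9.

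Largest in favour of the E11.5 cultured plate were the granulocyte genes S100a8, S100a9, Mpo and Elane (at least 345-fold, 191-fold, 148-fold and 146-fold higher) and Prtn3 (42.9-fold, 23.1 to 89.9), with 45.1% (Prtn3) to 53.7% (Mpo) of their counts in 1 well. They were followed by, among others, the limb and genital homeobox gene Hoxd13 (8.78-fold, 4.28 to 20.9), Sprr1a (25.1-fold, 8.36 to 124, on 3 counts, with 48.7% of the E11.5 cultured counts in 1 well), Jph4 (10.8-fold) and A2m (8.58-fold). Of the 7 and 18 E12.5 cultured counts of Jph4 and A2m 42.9% and 50% lay in 1 well. Lower were the globins Hba-a1 (at least 67.4-fold), Hbb-y (61.5-fold), Hba-x (60.1-fold) and Hba-a2 (49.9-fold, 13.3 to 419.7), the progenitor gene Crym (4.15-fold, 3.04 to 5.74), Corin (4.26-fold), Ano4 (3.94-fold), the mesenchymal factor Foxl1 (3.73-fold, 2.48 to 5.74), Bace2 (3.55-fold), Myh11 (3.08-fold, 2.59 to 3.70) and Col18a1 (2.75-fold), the last 2 with 42.2% and 40.1% of their E12.5 cultured counts in 1 well. Notch4 was 4.13-fold lower, but 77.0% of its E12.5 cultured counts lay in 1 well, and without wells over 3 times the median its log2 ratio was 0.0033.

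Of the remaining lists, early nephron stood at -0.05 (11 members), with Lhx1 9.87-fold lower (3.85 to 32.1) and 61.2% of its E12.5 cultured counts in 1 well. Renal transcription factors stood at -0.50 (percentile 0; 3 of 17 lower). Podocyte genes stood at -0.24 (percentile 5.93; mean 0.13), with Enpep 2.08-fold higher (1.57 to 2.80). The proximal tubule list stood at -1.76 (6 members; 1 higher, 3 lower), with Hnf4a 21.9-fold lower (3.40 to 917) on 1 count and Osr2 4.27-fold higher (3.21 to 5.78), and at 1.36 with members of at least 50 counts. Loop of Henle and distal tubule genes stood at -0.96 (percentile 0.07, 4 of 8 lower, 1 higher), with Sostdc1 2.80-fold lower (1.64 to 4.89). Of the 22 E11.5 cultured counts of Sostdc1 63.6% lay in 1 well. Ureteric epithelium stood at -0.02 (8 members; mean 0.37), with the ureteric tip gene Wnt11 2.34-fold higher (1.40 to 4.08). Epithelial adhesion and polarity genes were lower, at -0.88 (percentile 0; 8 of 16 lower, 0 higher), with the desmosome gene Dsp 5.24-fold lower (2.07 to 15.7). Endothelium stood at -1.38 (6 of 10 lower, 1 higher) but at 0.33 without wells over 3 times the median count; 80.9% of the E12.5 cultured counts of Plvap, 8.36-fold lower (4.48 to 16.8), lay in 1 well. Erythroid stood at -5.91 over 5 members, with E12.5 cultured counts of Hba-a1, Hba-x, Hbb-y and Hba-a2 spread over 47.5%, 47.0%, 44.0% and 24.5% of kept wells, while 1 multi-cell well of that plate held 98.1% to 99.1% of their multi-cell counts. Skeletal muscle stood at -0.20 over 2 members and coelomic epithelium and gonad at 0.81 over 5, with Upk3b 19.8-fold higher (5.21 to 167) on 2 counts and 48.2% of its E11.5 cultured counts in 1 well. Hypoxia and glycolysis genes were higher, at 0.45 (percentile 100; 3 of 20 at least 2-fold higher, 0 lower), with Ero1l 2.28-fold (1.88 to 2.78) and Slc2a3 2.08-fold (1.69 to 2.58) higher and Eno1 1.41-fold lower (1.32 to 1.5). Immediate early genes stood at 0.32, with Nr4a1 2.31-fold (2.10 to 2.54) and Hspa1a 2.32-fold (1.57 to 3.50) higher. Matrix genes stood at 0.28, with Cyr61 2.53-fold higher (2.29 to 2.79) and Col1a1 at 11105 against 7097 CPM. Cholesterol synthesis stood at -0.39 (percentile 0.01), with Fdps 2.70-fold lower (1.80 to 4.10). Proliferation stood at -0.23, with Mcm5 1.75-fold lower (1.51 to 2.04). Oxidative phosphorylation stood at -0.27, with Cycs 1.42-fold lower (1.06 to 1.91). Basement membrane stood at -0.11, with Col4a5 2.59-fold higher (1.63 to 4.26) and Lama1 2.41-fold lower (1.63 to 3.61). Lgr receptors and the Wnt pathway stood at 0.11, with Rspo3, a ligand of the Lgr receptors, 2.89-fold higher (2.28 to 3.71) and Wnt4 1.495-fold lower (1.32 to 1.70). Imprinted growth genes stood at 0.01, with Meg3 1.40-fold higher (1.35 to 1.46) and Peg3 1.54-fold lower (1.42 to 1.66). Interferon response stood at -0.02, with Isg15 4.44-fold lower (1.37 to 18.7). Of 64 genes taken here, 57 kept their direction under every alternative and 38 moved by over 1.5 times under at least 1.

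On each cultured plate 42 wells are labelled as holding more than 1 cell, and which cells were sorted into them is not given in the sources used here. These wells were rich in the lineage reporter and in nephron genes. tdTom stood at 462 CPM (411 to 518) against 75.3 in the single-cell wells of the E12.5 cultured plate, 6.13-fold higher (5.07 to 7.43), and at 524 CPM (469 to 584) against 63.8 on the E11.5 cultured plate, 8.22-fold higher (6.88 to 9.83). It was found in 33 of 42 (78.6%) and 27 of 42 (64.3%) of the wells. EGFP_IRES_Cre was not higher, with ratios of 0.603 (0.338 to 1.01) and 0.932 (0.530 to 1.55), and NeoR stood at 0.748-fold (0.502 to 1.09) and 1.99-fold (1.57 to 2.51). Six2 was 5.22-fold (4.30 to 6.34) and 4.77-fold (3.72 to 6.12) higher in them, Cited1 9.82-fold (7.56 to 12.9) and 5.07-fold (3.21 to 8.02), Pax2 7.28-fold (5.77 to 9.21) and 2.93-fold (2.09 to 4.08), and Lgr4 2.06-fold (1.53 to 2.77) and 2.99-fold (2.32 to 3.84). Lgr5 was 7.92-fold (2.81 to 25.4) and 7.10-fold (1.94 to 28.4) higher, but 46.2% of its 13 counts in these wells lay in 1 well of the E12.5 cultured plate and all 7 in 1 well of the E11.5 cultured plate. Wt1 was 3.08-fold (2.66 to 3.57) and 1.20-fold (1.02 to 1.41) higher. Lgr6, with 2 counts and 1 count in these wells, showed no detectable difference. The wells held 642839 and 632925 counts, with medians of 10478 and 7535 per well, and the deepest held 8.60% and 26.7% of them.

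On the E12.5 cultured plate the nephron progenitor median of multi-cell over single-cell wells was 2.45 (percentile 100; 9 of 12 members higher, 0 lower), early nephron 2.34 (8 of 11 higher), podocyte 1.72 (8 of 12 higher), loop of Henle and distal tubule 2.90 (10 of 11 higher), epithelial adhesion and polarity 2.18 (13 of 16 higher) and renal transcription factors 1.62 (9 of 17 higher, 1 lower). Uncx was 9.08-fold (7.38 to 11.2), Cdh16 9.20-fold (7.08 to 12.1), Pax8 8.27-fold (6.07 to 11.4) and Cdh1, E-cadherin, 7.12-fold (4.75 to 10.8; 40.6% of its counts in 1 well) higher. Fgf8 was 39.0-fold (12.2 to 199) higher on 3 single-cell counts, while Itga8 stood at 80.9 against 85.1 CPM. Bmp7 was 12.1-fold (8.11 to 18.4), Tfcp2l1 14.5-fold (46.6% in 1 well), Wfdc2 11.4-fold, Pcp4 13.2-fold (47.5%), the merged feature Pcp4-cluster 15.2-fold (45.7%), Ly6a 10.6-fold and Fxyd2 12.4-fold higher, the last with 69.9% of its counts in 1 well. Of the counts of Slc12a1 (42.2-fold higher) 98.1% lay in 1 well, as did 98.1% to 99.1% of those of the globins Hbb-y (92.6-fold), Hba-a2 (53.0-fold), Hba-a1 (49.3-fold) and Hba-x (47.5-fold). Stroma and matrix genes were lower, at -1.80 (12 of 16 lower, 0 higher) and -1.63 (13 of 16 lower), with Acta2 10.0-fold (8.07 to 12.6), Tagln 10.0-fold, Actg2 14.7-fold, Myh11 14.2-fold, Igfbp3 19.2-fold (9.25 to 48.0), Myl9 6.30-fold, Serpina3g 9.40-fold and Tbx18 5.45-fold (3.13 to 10.4) lower. Of the single-cell counts of Igfbp3, Myh11 and Sst 49.7%, 42.2% and 45.0% lay in 1 well. Sst, Synpo2 and Aspn had 1 count each in these wells, ratios of 37.4-fold (6.62 to 1491), 30.9-fold (5.44 to 1232) and 27.6-fold (4.85 to 1102) lower, and Vcam1 and Osmr none, at least 6.75-fold and 6.57-fold lower. Endothelium stood at -2.55, and at -0.997 with wells weighted equally, where 80.9% of the single-cell counts of Plvap lay in 1 well, and macrophage and other leukocyte at 1.54 with C1qc 3.81-fold higher (3.06 to 4.75; 53.7% of its counts in 1 well). Interferon response stood at -1.66 and imprinted growth genes at -0.72 with Igf2 2.56-fold (2.41 to 2.73) and Dlk1 3.08-fold (2.59 to 3.69) lower. Smaller medians were seen for proliferation (0.23; Rrm2 1.68-fold higher, 1.37 to 2.05), immediate early genes (-0.44; Junb 2.10-fold lower, 1.76 to 2.52), hypoxia (-0.28; P4ha1 2.03-fold lower, 1.61 to 2.58), oxidative phosphorylation (0.40; Cox5a 1.71-fold higher, 1.45 to 2.02), cholesterol synthesis (-0.37; Dhcr7 2.09-fold lower, 1.36 to 3.34) and basement membrane (0.16; Lama1 3.90-fold higher, 2.80 to 5.43, and Nid1 3.03-fold lower, 2.38 to 3.91). Lgr receptors and the Wnt pathway stood at 0.40, and at -0.23 with wells weighted equally, with Nkd1 1.83-fold lower (1.45 to 2.36) and Tgfbi of the matrix list 1.19-fold lower (1.03 to 1.38).

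On the E11.5 cultured plate the nephron progenitor median was 1.94 (percentile 100; 9 of 12 higher, 1 lower), early nephron 1.10 (6 of 12 higher, 1 lower), podocyte 1.02 (6 of 11 higher), loop of Henle and distal tubule 2.20 (6 of 10 higher, 1 lower), epithelial adhesion and polarity 1.62 (9 of 15 higher) and renal transcription factors 0.47 (7 of 16 higher, 1 lower). Uncx was 7.95-fold (5.69 to 11.2), Meox1 8.46-fold (3.47 to 21.9), Npnt, a podocyte list gene, 6.01-fold (4.51 to 8.02), Foxc1 4.76-fold (3.73 to 6.06), Pard6b 7.25-fold (4.01 to 13.3) and Gadd45a 3.87-fold (3.04 to 4.91) higher, while Itga8 stood at 94.8 against 91.3 CPM. Several others had a large share of their counts in 1 well: Spp1 (39.1-fold; 91.9% of its counts), Sprr1a (11.48-fold; 72.8%), Foxd1 (3.88-fold; 71.6%), Col4a3 (10.1-fold; 70.0%), Fgf8 (60.9-fold; 66.7%), Podxl (10.5-fold; 51.4%), Dsp (6.76-fold, 2.06 to 23.7; 50%), Lgals3 (10.7-fold; 50.6%), Clic5 (22.8-fold; 46.8%), Col4a4 (16.02-fold; 45.1%) and Crym (5.90-fold, 4.05 to 8.62; 42.3%). Without the deepest labelled well the log2 ratio of Foxd1 went from 1.96 to 0.59. Lower were neural genes, at -1.24 (percentile 0.01; 5 of 10 lower, 0 higher), among them Stmn2 (12.8-fold, 6.70 to 28.2; 44.1% of its single-cell counts in 1 well), with Gap43 (13.9-fold, 5.91 to 43.1; 48.8%), Dpysl3 (4.95-fold) and Elavl2 (31.4-fold, 5.54 to 1246, on 1 count) outside the list. So were the granulocyte genes Mpo (29.9-fold), S100a9 (17.1-fold), S100a8 (13.3-fold), Prtn3 (6.08-fold) and Elane (5.89-fold), with 45.1% (Prtn3) to 53.7% (Mpo) of their single-cell counts in 1 well. The macrophage list stood at -0.57 with C1qa 9.53-fold lower (4.32 to 26.2), and endothelium at -0.77, or -2.64 with wells weighted equally, with Kdr 5.92-fold lower (2.25 to 22.1). Also lower were Xist, the RNA of the inactive X chromosome (5.24-fold, 4.28 to 6.499), where Y-linked transcripts stood at 259 against 130.5 CPM, Inhba (8.91-fold) and Gdf10 (6.42-fold). The stroma median was -0.15, with Alx1 3.75-fold lower (1.85 to 8.83), and the ureteric median 0.18 (mean -0.41), with Gata3 7.39-fold lower (1.98 to 62.2) on 2 counts. Hypoxia genes stood at 0.51 with Pfkp 3.21-fold higher (2.55 to 4.02), and immediate early genes at 0.41 with Atf3 1.91-fold higher (1.52 to 2.39; 46.4% of its counts in 1 well). Proliferation stood at -0.27 with Mcm5 2.24-fold lower (1.52 to 3.42) and Ccnb1 at a ratio of 1.54 (1.14 to 2.06) with 48.5% of its counts in 1 well, and basement membrane at 0.19 with Nid1 1.71-fold lower (1.45 to 2.04). Oxidative phosphorylation stood at 0.04 with Cox4i1 1.29-fold higher (1.14 to 1.45). Of the genes taken for these wells, 55 of 56 on the E12.5 cultured plate and 51 of 52 on the E11.5 cultured plate kept their direction under every alternative, and 22 and 21 moved by over 1.5 times under at least 1.

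The level of genes within nephron progenitor-like cells was to be compared between plates with at least 20 such cells, and only the uncultured plate, with 92, had them. Cells with at least 2 of Six2, Cited1, Meox1, Crym and Dapl1 detected numbered 124 on the uncultured plate (36.8%), 28 on the E12.5 cultured plate (14%) and 13 on the E11.5 cultured plate (4.33%), a choice that depends on depth. Of these, 72, 8 and 3 lay in the nephron progenitor-like cluster and the rest in other clusters, so the levels in them are those of different mixtures of cells. In them Wt1 stood at 800.4 CPM (766 to 836), 263 (221 to 309.9) and 380.4 (307 to 467), Pax2 at 382 (358 to 406), 96.2 (71.7 to 127) and 244 (186 to 315), and Eya1 at 296 (276 to 318), 49.1 (32.1 to 71.9) and 78.6 (47.3 to 123). Sall1 stood at 179.7 CPM (164 to 197), 66.1 (46.0 to 91.9) and 103 (66.9 to 153). Osr1 did not differ beyond counting error, at 96.0 (84.4 to 109), 113 (86.4 to 146) and 124 (83.7 to 177) CPM. Lgr6 had 9, 3 and 0 counts in these cells, out of 9, 5 and 12 in all kept wells of the 3 plates.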

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

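All tests in this part were chosen only after the result was seen.

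NeoR transcripts lay outside the comparisons of the design and were found in a larger share of kept than of control wells after culture. They were found in 38.0% of kept wells of the E12.5 cultured plate (31.2 to 45.1) against 0 of 15 control wells, which allows up to 20%, and in 41.0% of the E11.5 cultured plate (35.4 to 46.8) against 6.67% (upper limit 31.9%). On the uncultured plate NeoR was found in 27.6% of kept wells and in 20% of control wells. Control wells of the E12.5 and E11.5 cultured plates had medians of only 129 and 150 counts, against 9212 and 8992.5 in kept wells. They may also understate stray RNA, as set out in the next paragraph. Whether NeoR stood above stray transcripts is thus not settled by these shares.

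tdTom and EGFP_IRES_Cre were found in many kinds of cells on the cultured plates. Xist and Y-linked transcripts were found together in 20% and 24.0% of kept wells of the E12.5 and E11.5 cultured plates. Stray RNA or doublets in kept wells may thus add to the reporter shares, which was not tested. The tables argue against counting of tdTom transcripts as EGFP_IRES_Cre, since EGFP_IRES_Cre in multi-cell over single-cell wells was at most 0.932 (0.530 to 1.55) where tdTom was 8.22-fold higher. Whether nephron cells carry most of the tdTom label stays open: the ratio of its CPM in nephron progenitor-like and epithelial cells over other cells was 0.732 (0.435 to 1.16), but stray transcripts would level the cell types, and multi-cell wells, rich in nephron transcripts, held 6.13-fold and 8.22-fold more tdTom. Free RNA or barcode exchange between wells stays open: control wells held at most 24.3% of the tdTom and 30.6% of the EGFP_IRES_Cre counts of a kept well, and an earlier reading of these bounds as excluding it was wrong, because granulocyte transcripts were 14.2 times as frequent per kept well outside their 5 top wells as per control well, so control wells may understate stray RNA. That factor rests on 1 control count of the E11.5 cultured plate. On the E12.5 cultured plate S100a8, S100a9, Mpo and Elane had no count in kept or control wells, so no factor could be computed there. Applied to both cultured plates together, the factor takes tdTom, with 1 count in 30 control wells, to 62.1% and EGFP_IRES_Cre to 0%. Their scaled upper limits of 346% and 435% leave out the counting error of the factor, so they are not exact limits. Expression of the knock-in or label in many cell types after culture, untested here, stays open beside free RNA or barcode exchange.

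Multi-cell wells held far more tdTom and nephron transcripts than single-cell wells. The tables argue against 1 deep well as the cause, since without it the tdTom ratio of the E11.5 cultured plate was 10.4 (8.69 to 12.47), and against depth, since labelled wells at or under the plate's median count had a tdTom ratio of at least 10.3 (7.56 to 13.9, the lower of both plates). Whether cells were sorted through another gate cannot be told apart from other causes, because 0 of the samples have labels that record a gate. On the E11.5 cultured plate Xist stood at 152 CPM in multi-cell and 795 CPM in single-cell wells and Y-linked transcripts at 259 and 130.5 CPM. A difference in which cells were sorted, such as a choice of tdTom-bright cells, or in which embryos or explants they came from, is a hypothesis consistent with these values and was not tested.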

How the results depend on the processing

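Chosen after seeing the data (added) were a minimum of 3000 counts, leaving Gm42418 out of the total, thinning for the reporters, leaving out labelled wells under 1000 counts or the deepest one, and naming clusters without the rule on leading genes. No paired analysis was possible because each group had 1 plate and no fit was made. Depth limits Lgr6, with 9, 4 and 8 cells holding it, and cells with few counts cannot show its absence. Where a value moved or turned, the cause was not tested.

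Over 13 alternatives the stroma list stayed higher than on the uncultured plate, at 2.09 to 2.55 on the E11.5 cultured plate (main value 2.37) and 2.08 to 2.43 on the E12.5 cultured plate (2.38), and the nephron progenitor list stayed lower, at -3.16 to -2.01 (-2.49) and -2.42 to -0.72 (-1.33). Between the cultured plates the progenitor list ran from -1.90 to 0.42 (-0.88). It took the other sign in odd plate columns and stayed lower under the other alternatives, so its direction was not stable. In multi-cell wells it ran from 2.11 to 2.45 on the E12.5 and from 1.93 to 2.07 on the E11.5 cultured plate. Over genes taken by the naming rule and alternatives, 2296 values stayed within their counting interval, 380 left it and 6 took the other sign against an interval that excludes 0. Of the first kind 16 and of the second 16 also had the other sign, from intervals that include 0. Over lists not counted among the main results these numbers were 845, 170 and 18, with 22 and 13. The median of all genes moved to 0.13 with mitochondrial genes in the total for the E11.5 cultured plate over the uncultured plate (0.07 without) and to -0.11 with median-of-ratios scaling for the E12.5 cultured plate; the ratios in the report stand relative to the total.

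For the E11.5 cultured over the uncultured plate, the mean of per-cell CPM gave -2.17 for progenitor, 2.09 for stroma and -0.12 for imprinted genes, and median-of-ratios scaling 2.26 for stroma and -0.056 for imprinted genes. Without wells over 3 times the median, progenitor genes stood at -2.01, macrophage at -0.039 and imprinted at -0.079. Odd columns gave progenitor -2.14, loop of Henle -1.22, ureteric -2.08 and imprinted -0.0026, and even columns progenitor -3.16 and stroma 2.55. With members of at least 50 counts the loop of Henle list stood at -1.24.

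For the E12.5 cultured over the uncultured plate, the mean of per-cell CPM gave progenitor -0.74 and stroma 2.08, and leaving out wells over 3 times the median gave progenitor -0.72 and erythroid 1.20. Odd columns gave progenitor -2.42, macrophage 0.33 and epithelial adhesion -0.086, and even columns progenitor -1.03, erythroid 1.06 and Cited1 0.027. A pseudocount of 0.5 gave progenitor -1.04, and a minimum of 50 counts gave loop of Henle -0.63 and epithelial adhesion -0.054.

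For the E11.5 over the E12.5 cultured plate, leaving out wells over 3 times the median gave endothelium 0.33 and Notch4 0.0033. Odd columns gave progenitor 0.42, stroma -0.16, Six2 0.68, Cited1 0.42 and Pax2 0.11, and even columns progenitor -1.90, endothelium 0.93 and Notch4 0.54. With at least 50 counts the proximal tubule list stood at 1.36. In multi-cell wells the mean of per-well CPM gave -0.23 for the Lgr and Wnt list of the E12.5 cultured plate, and tdTom on the E11.5 cultured plate a log2 ratio of 3.46, or 3.38 without the deepest labelled well (added), against 3.04.

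The share of wells kept on the uncultured plate was 95.4% with a minimum of 500 counts, 85.1% with 2000 and 80.2% with 3000 (added), and that of the E11.5 cultured plate 88.1% with 3000 (added). Lgr6 was found in 0%, 0% and 0.667% of cells thinned to 1000 counts and in 0.318%, 0.513% and 1.01% thinned to 2000, with 23, 5 and 3 shallower cells left out; at least 2 counts were found in 0%, 0.5% and 1.33%. The progenitor-like share was 35.3% of uncultured and 10.0% of E12.5 cultured cells at resolution 0.5, 1.5% of E12.5 and 0.333% of E11.5 cultured cells at 2.0, and 13.5% and 8.33% with each plate clustered alone. The stroma-like share was 46.0% and 46.7% of E12.5 and E11.5 cultured cells at 0.5, and 14.8%, 43.5% and 22.3% of the 3 plates at 2.0. It was 20.5% of uncultured cells clustered alone, 35.7% of E11.5 cultured cells without the proliferation list and 57.7% without the rule on leading genes (added), and 54.0%, 88.5% and 91.7% when cells were assigned from markers without clusters.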

Other observations

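In this part the test of the spread of granulocyte transcripts was set out before its result was seen, and the other values, with the choice of genes, were picked after they had been seen.

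Several clusters of cultured cells stayed unnamed. A cluster led by Tm4sf1, Actg2, Tagln, Acta2, Mgp and Eln held 17 E12.5 cultured cells (8.5%) and 18 E11.5 cultured cells (6.0%), with 8 podocyte markers such as Podxl and 6 stroma markers. Clusters led by Cxcl13, Slc38a5 and Col25a1 (53 and 29 cells) and by Nrxn3, Cck, Nts, Corin and Wnt4 (25 and 22 cells) held no uncultured cell, nor did one with the mitosis genes Aurkb and Foxm1 among its leading genes (12 and 20 cells).

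Sex-linked transcripts differed between the plates. Cells with Xist and no counted Y-linked transcript made up 18.99% of the uncultured plate, 55.5% of the E12.5 cultured plate and 51.0% of the E11.5 cultured plate, and cells with Y-linked transcripts and no Xist 51.0%, 20.5% and 21%. Both kinds were found together in 15.4%, 20% and 24.0% of kept wells. In multi-cell wells of the E12.5 and E11.5 cultured plates they were found together in 33.3% and 45.2%. Kept wells with both kinds may hold transcripts of several cells, through stray RNA or doublets, which was not tested. Shares of kept wells with Lgr6, EGFP_IRES_Cre or tdTom thus need not equal the shares of cells that express them.

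S100a8, S100a9, Mpo and Elane, transcripts of maturing granulocytes, were counted in 176 of 300 kept wells of the E11.5 cultured plate. Of their 3403.6 counts 91.8% lay in 5 wells, and the other kept wells held 0.949 counts each on average against 0.0667 per control well. A candidate explanation is that few granulocyte-like cells gave most of these transcripts and that the rest spread to other wells before or after the sort; which of these happened was not tested.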
